A study of Mus musculus with 6 samples.

How the data were processed

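RNA of sorted Yap-expressing mouse liver cells was extracted with a Qiagen micro RNeasy kit, amplified and labelled with a Nugen Pico WT kit and biotin, and hybridised to microarrays, per the labels' protocols. The labels give 3 arrays at 1 week and 3 at 6 weeks after induction, with a number from 1 to 3 in each group. The values are intensities per probe set that the authors deposited after RMA, per the submitters' processing notes; RMA corrects the background, normalizes between arrays and summarises the probes of a set. The version of RMA, the software and the arrays normalized together are not given in the sources used here. Medians of about 15 and maxima of 8980.9 to 11283 show that the deposited intensities are linear, so log2 was taken of them first; the design fixed before the data were examined had assumed values already on a log2 scale. Both tables hold identical values for the 6 arrays, so the alternative of using the other table changed nothing. A further 3 columns of the complete table, from fetal liver arrays of another series, were not used, and the comparison with fetal liver is not analysed here.

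Probe sets were named from the platform annotation. Of 34760 probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 had none; 21553 of the 1-symbol probe sets matched a gene ID of the reference gene table. Only 1-symbol probe sets were named, which gave 19937 genes, and of the 954 genes with several such probe sets the one with the highest mean over the 6 arrays was kept. Among the named genes this choice mattered for Clec4g, whose probe sets disagree on the call, and for the size of the difference of Idi1. Spp1, which the rule below names, is not analysed here, and 1 further item is not reported here. No genome build is named in the sources used here, so no coordinates are given. The deposited intensities carry no detection calls: the median log2 intensity over all probe sets was 3.98, and differences of genes near that level are compressed by background. Saturation near the highest intensities was not tested.

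Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the prior variance on intensity), over the 6 arrays with no covariate and no filter on dim probe sets, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was run per gene. The genes named in the text were set by a rule: the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays do not overlap, up to 4 members of each list with the smallest p, and 17 genes named whatever their values. The few others, among them Ccnd1, Mcm4, Mcm2, Col14a1, Col3a1, Col1a2 and Col1a1, were chosen after their values were seen.

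Lists of genes were fixed before the data were examined: YAP/TEAD targets, Hippo components, biliary and progenitor markers, the Notch pathway, hepatocyte secreted and metabolic genes, cytochrome P450 and bile acid genes, pericentral, periportal and fetal liver genes, the cell cycle, TGF-beta and mesenchymal transition, fatty acid oxidation, lipogenesis, cholesterol synthesis, acute phase, interferon response, immediate early and clock genes, and markers of stellate cells, macrophages, lymphocytes, endothelium, erythroid cells, neutrophils and sex, 25 in all. They were tested with camera of limma, which asks whether a list differs from all other genes, with a preset correlation of 0.01 and adjustment over the lists. A correlation estimated for each list was run beside it. So was fry, which asks whether the genes of a list move one way on balance and compares the list with no other genes; its mixed p, which asks for change in either direction, is not reported. Ahsg is in the lists of hepatocyte and fetal liver genes, and the other lists share no member.

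The replicate numbers were checked for pairing. Deviations of arrays from their group means correlated at 0.13, 0.18 and 0.11 between arrays of the same number, all over the 0.1 set beforehand, and at -0.13 to 0 between others. The numbers met that criterion. Deviations from a group mean cancel out within the group, so positive values between equal numbers force lower ones between others. Correlations this small do not show that the arrays are paired, and the labels do not state it. Pairing thus stays open, and the block on the replicate number is given where it changes a call.

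Alternatives fixed beforehand were eBayes without the trend or with the robust option, array weights, quantile normalization again, median centring, bright probe sets only (17380 at or above the median), the mean or the most variable of a gene's probe sets, probe sets in place of genes, the block, each array left out in turn, a stricter adjusted p of 0.01, a minimum of 2-fold, and a plain two-sample test per gene. The fit was tested on simulated data for the same 19937 genes with 200 changed: it recovered 32.8% of genes changed by 0.5 on the log2 scale, 70.1% of those changed by 1 and 97% of those changed by 2, with 3 false calls among 136. In the data 2242 genes passed, a larger share. Recovery after adjustment depends on that share, so these rates do not give the sensitivity of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.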

Results

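Gene expression was measured on 6 microarrays hybridised with RNA from mouse liver cells that express the transcriptional coactivator Yap, the effector of the Hippo growth control pathway. Expression of Yap was switched on with doxycycline in inducible mice on a C57Bl6 background that carry a YFP reporter in the Rosa26 locus. Yap-expressing cells were purified from the liver by fluorescence-activated sorting 1 week (n = 3 arrays) or 6 weeks (n = 3 arrays) after induction. Each array gave 34760 probe set values, and the median intensity lay between 15.02 and 16.58. The number of arrays limits the precision. Correlations of log2 values lay between 0.989 and 0.99 among the 1-week arrays, between 0.979 and 0.98 among the 6-week arrays, and between 0.96 and 0.974 across the times. The 6-week arrays had a narrower range of values, with an interquartile range of 3.22 to 3.32 on the log2 scale against 3.41 to 3.44 at 1 week.

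The comparison asked how the expression of Yap-expressing liver cells differed between 6 weeks and 1 week of induction. All 6 arrays are of Yap-expressing cells, with no uninduced control at either time. Effects of longer Yap expression thus cannot be told apart from those of time on doxycycline or of the age of the mice. Differences are given as log2 intensity at 6 weeks minus 1 week, ± the standard error, with n = 3 arrays per time. The genes with the largest rises included Car3 (carbonic anhydrase; 3.39 ± 0.41), the small heat shock protein Hspb1 (3.25 ± 0.28) and the carboxylesterases Ces1d (3.18 ± 0.37) and Ces1g (3.15 ± 0.28). The other rises among the largest 12 included the tight junction claudin Cldn6 (3.17 ± 0.20), the surface protein Plet1 (3.08 ± 0.25), the glucose transporter Slc5a1 (3.03 ± 0.26), the secreted protease inhibitor homologue Wfdc2 (3.02 ± 0.17), the apical bile acid transporter Slc10a2 (2.97 ± 0.33) and the cadherin Cdh6 (2.92 ± 0.30). Dcn, which encodes the matrix proteoglycan decorin, rose by 2.83 ± 0.25, and Rgs5, a gene of pericytes, by 2.81 ± 0.10.

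The genes with the largest falls included regulators of mitosis. Mki67, the gene of the proliferation antigen Ki67, went from 8.29 ± 0.20 to 4.91 ± 0.33 (log2 intensity ± SD, n = 3), a difference of -3.38 ± 0.19. The differences were -3.34 ± 0.21 for the mitotic spindle gene Hmmr, -3.31 ± 0.10 for the cyclin gene Ccnb2, -3.29 ± 0.19 for Cdca3, -3.21 ± 0.20 for Birc5 and -2.86 ± 0.20 for the mitotic kinase gene Plk1. Retnlg, a neutrophil gene, had the largest fall (-3.48 ± 0.33), and Chil3, a chitinase-like gene of monocytes and macrophages, had -2.89 ± 0.46. The other falls among the largest 12 were in genes of transport and metabolism: the organic anion transporter Slco1a4 (-3.35 ± 0.40), the sulfotransferase Sult1d1 (-3.02 ± 0.26), the fatty acid binding protein Fabp2 (-2.95 ± 0.24) and Cyp8b1, the sterol hydroxylase of cholic acid synthesis (-2.92 ± 0.32). Adjusted p-values of the 24 genes with the largest rises and falls lay between 0.000193 (Ccnb2 and Rgs5) and 0.0122 (Chil3). Chil3 lost its call without 1-week array 2 or 3 or without 6-week array 3 (adjusted p up to 0.073, with 0.0014 to 0.073 over its alternatives).

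**Figure D1:**
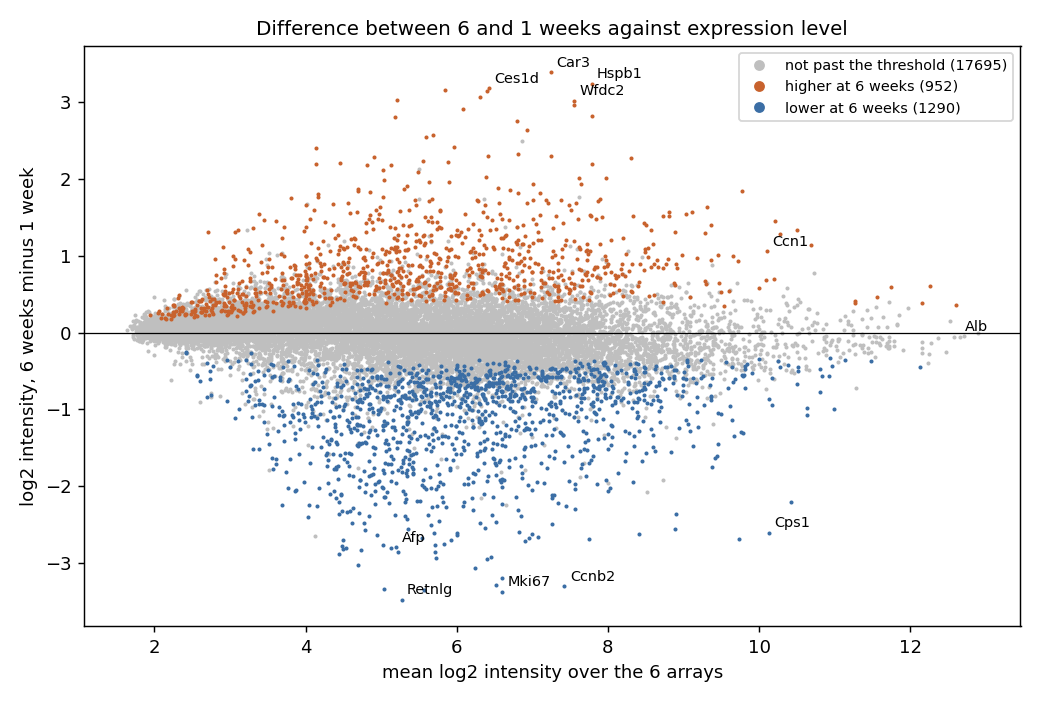
Difference of log2 intensity between 6 weeks and 1 week (vertical axis) against the mean log2 intensity over the 6 arrays (horizontal axis), with 1 point per gene. Orange points are the 952 genes higher and blue points the 1290 genes lower at 6 weeks at an adjusted p under 0.05, grey points are the other genes, and the labelled extremes include Car3 (3.39) and Mki67 (-3.38).

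Of 19937 genes, 2242 passed an adjusted p of 0.05 in limma's moderated test, 952 higher and 1290 lower at 6 weeks. In each of these 2242 genes all 3 arrays of one time lay beyond all 3 of the other, as they did in 6771 genes (34%) in total, where chance gives 10%. The median difference over all genes was 0.04, and it was -0.13 for 5901 genes with a mean log2 intensity of 6 or more and 0.07 for the 14036 dimmer genes. With 1 array left out, the count was 827, 707 and 963 without 1-week array 1, 2 and 3, and 1018 without 6-week array 3. Without 6-week array 2 the genes lower fell to 796 of 1527. A plain two-sample test per gene, which takes no information from other genes, called 296 genes. Of the 105 genes named by rule that passed, 57 kept the call without each of the 6 arrays and 48 lost it without at least 1. The labels do not say that the arrays come from separate animals, so p-values measure only the spread between these samples. They also give no processing dates, so batch and time point cannot be told apart.

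Genes driven by Yap and its DNA-binding partners of the TEAD family rose more often than they fell. Of 24 measured YAP/TEAD target genes, 6 rose and 2 fell (10 and 2 when adjusted over the list alone), with a median of 0.36. The secreted matrix protein gene Ccn1, a much used read-out of Yap activity, rose from 9.57 ± 0.18 to 10.63 ± 0.26 (1.06 ± 0.16, adjusted p = 0.0099), as did the growth factor gene Tgfb2 from 4.83 ± 0.15 to 6.33 ± 0.21, the phosphatase gene Ptpn14 (1.38 ± 0.16) and Ankrd1 (0.74 ± 0.09). Nt5e, the gene of the surface enzyme that makes adenosine, fell by 1.87 ± 0.16 on the log2 scale. Ccn2, another standard target, had 9.69 ± 0.16 at 1 week and 9.77 ± 0.27 at 6 weeks (0.08 ± 0.16, adjusted p = 0.756), and its sign turned without 1-week array 3 (-0.01) or 6-week array 3 (-0.02). The list passed the competitive test against all other genes (adjusted p = 0.00379), with adjusted p = 0.36 with an estimated correlation, and in the same arrays immediate early genes had a median of 0.71 and stellate cell markers of 0.48. Ccn1 lost its call without 1-week array 1 or 2 (adjusted p up to 0.057, with 0.0036 to 0.057 over its alternatives).

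Yap1 itself read 6.70 ± 0.12 at 1 week and 7.23 ± 0.18 at 6 weeks (0.53 ± 0.13, adjusted p = 0.0455). The labels do not give the sequence of the transgene, so whether this probe set reads it is not known. Among 19 measured Hippo pathway components, 4 rose and 0 fell (5 and 0 when adjusted over the list alone): Yap1, Vgll4, a competitor of Yap for TEAD (0.78 ± 0.15), the scaffold gene Amotl1 (0.62 ± 0.15) and Frmd6 (1.08 ± 0.27). The list's median was 0.18 and the list did not pass (adjusted p = 0.1), but it did after quantile normalization (0.00274), after median centring (0.047), with bright probe sets only (0.0159) and without 6-week array 3 (0.045), in a range of 0.0027 to 0.54 over its alternatives. With the replicate number as a block, Yap1 had an adjusted p of 0.0767 and Frmd6 of 0.0528, and Yap1 also missed the threshold after median centring (0.0868) and Frmd6 without the intensity trend (0.0536) and with array weights (0.0637). Yap1 and Vgll4 kept the call only without 6-week array 2, and Amotl1 and Frmd6 lost it without any array (adjusted p up to 0.15, 0.085, 0.12 and 0.15), with lowest values over the alternatives of 0.02, 0.0085, 0.023 and 0.022.

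**Figure D2:**
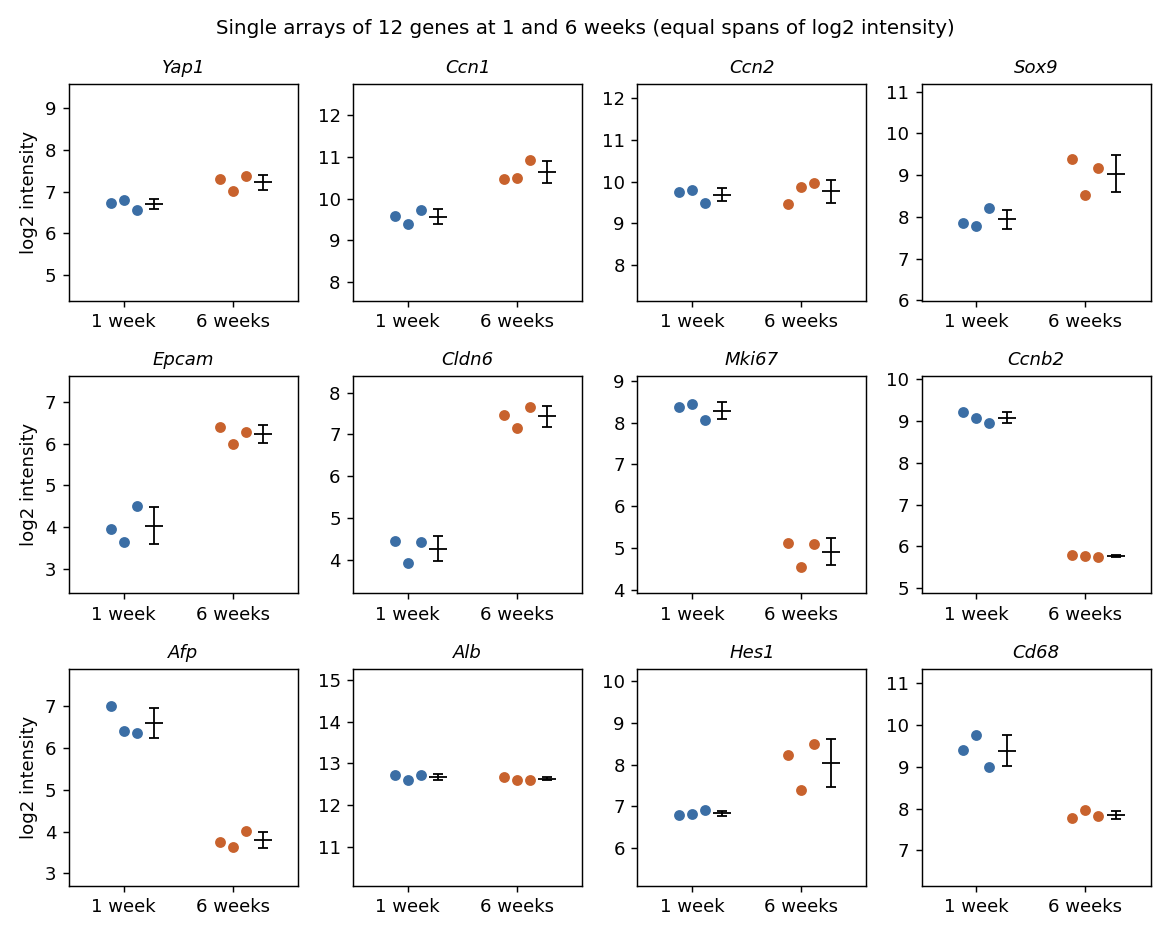
Log2 intensity (vertical axes, equal spans) of 12 genes on the 3 arrays at 1 week (blue) and the 3 at 6 weeks (orange), with the mean and SD of each time beside the points. The arrays of the times lie apart for Mki67 (means 8.29 and 4.91) and Cldn6 (4.26 and 7.43), and overlap for Ccn2 (9.69 and 9.77) and Alb (12.68 and 12.63).

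Markers of bile duct cells and liver progenitors were higher at 6 weeks. Of 24 measured members 14 rose and 0 fell (16 and 0 when adjusted over the list alone), with a median of 0.78. Cldn6 rose by 3.17 ± 0.20, the surface adhesion gene Epcam went from 4.04 ± 0.44 to 6.23 ± 0.21 (2.19 ± 0.23, adjusted p = 0.00327), Pkhd1, the fibrocystin gene of the cholangiocyte cilium, rose by 1.72 ± 0.13 and the surface antigen gene Cd24a by 1.94 ± 0.23. The duct transcription factor gene Sox9 rose from 7.94 ± 0.23 to 9.03 ± 0.44 (1.09 ± 0.23, adjusted p = 0.032). Krt19, a duct keratin, had 0.67 ± 0.28 (adjusted p = 0.174). The list passed (adjusted p = 2.11e-09), with adjusted p = 0.36 with an estimated correlation, and in the same arrays the stellate cell markers had a median of 0.48. Sox9 kept its call only without 6-week array 2 (adjusted p up to 0.13), and Krt19 passed without 1-week array 3, in a range of 0.031 to 0.39 over its alternatives.

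Genes of the Notch pathway passed the test about as often as all genes, of which 2242 of 19937 passed. Of 24 measured members, 2 rose and 1 fell (2 and 1 when adjusted over the list alone). The receptor gene Notch1 rose by 0.91 ± 0.17 (adjusted p = 0.0224) and the Notch target gene Hes1 by 1.20 ± 0.27 (adjusted p = 0.0359), while Adam10, the gene of the protease that cleaves Notch receptors, fell by 0.50 ± 0.11 on the log2 scale (adjusted p = 0.0341). Notch2 (0.19 ± 0.15), Jag1 (0.26 ± 0.09) and Lfng (-0.71 ± 0.21) did not pass, although Lfng did with the block (adjusted p = 0.0477), after median centring and with bright probe sets only, in a range of 0.044 to 0.19. The list had a median of 0.07 and a mean of 0.04, beside a median of 0.04 over all genes. The competitive test, which compares with all other genes and not with 0, pointed down (adjusted p = 0.995). Its direction turned in several alternatives. Adam10 missed the threshold with the block (0.0548), after quantile normalization (0.0561) and without any 1 array. Hes1 kept its call only without 6-week array 2, and Notch1 lost it without any 1-week array or 6-week array 2 (adjusted p up to 0.11, 0.13 and 0.097 for Adam10, Hes1 and Notch1).

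Secreted and metabolic genes of hepatocytes passed the test about as often as all genes (2242 of 19937). Alb, the albumin gene, read 12.68 ± 0.07 and 12.63 ± 0.04 (-0.06 ± 0.06, adjusted p = 0.576), near the highest intensities of the arrays, where saturation is not excluded. Hnf4a, the gene of a central hepatocyte transcription factor, had -0.38 ± 0.15 (adjusted p = 0.148). Of 31 measured members 1 rose and 3 fell (1 and 3 when adjusted over the list alone), with a median of -0.06. The gene that fell the most was Cps1, of the first step of the urea cycle, from 11.43 ± 0.19 to 8.82 ± 0.18 (-2.61 ± 0.14, adjusted p = 0.000694). Arg1, also of the urea cycle, had -0.88 ± 0.19, Tdo2, of tryptophan breakdown, -0.87 ± 0.17, and the transthyretin gene Ttr 0.39 ± 0.07. The list passed with its lower values (adjusted p = 0.0167), with adjusted p = 0.64 with an estimated correlation, and it lost the call after quantile normalization (0.0924), with bright probe sets only (0.343) and without 1-week array 1 (0.152) or 6-week array 2 (0.0621) or 3 (0.163), and by fry (0.269), in a range of 0.00064 to 0.64. Its median was no lower than that of random lists matched on mean expression (percentile 86.4, with 95% of them between -0.29 and 0.01). Ttr, which also missed the threshold after median centring (0.0963), lost its call without 1-week array 1 or 2 or 6-week array 2 or 3, Arg1 without 1-week array 1 or 3 or 6-week array 2 or 3, and Tdo2 without any array but 6-week array 1 (adjusted p up to 0.095, 0.11 and 0.092, from lowest values of 0.015, 0.016 and 0.011 over the alternatives).

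Genes of bile acid synthesis, cytochrome P450 and drug handling moved both ways. Of 27 measured members 2 rose and 5 fell (2 and 9 when adjusted over the list alone), with a median of -0.27. Cyp8b1 (-2.92 ± 0.32) and Slco1a4 (-3.35 ± 0.40) fell, as did the canalicular phospholipid transporter gene Abcb4 (-0.77 ± 0.12), while Cyp7b1, of the alternative pathway of bile acid synthesis, rose by 2.29 ± 0.18. Cyp7a1, the rate-limiting enzyme of the classic pathway, had a low reading at both times (3.12 ± 0.50 and 2.65 ± 0.28; -0.47 ± 0.26, adjusted p = 0.265). The list passed with lower values (adjusted p = 0.00335), with adjusted p = 0.48 with an estimated correlation and a false discovery rate of 0.0963 by fry, in a range of 0.00061 to 0.48. In the same arrays the macrophage, neutrophil and stellate cell markers had medians of -1.31, -0.76 and 0.48. Abcb4 lost its call without 1-week array 2 or 3 (adjusted p up to 0.057, from a lowest value of 0.0036 over its alternatives).

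Neither list of zonated hepatocyte genes passed as a whole. Among 18 pericentral genes 3 rose and 3 fell (3 and 3 when adjusted over the list alone; median 0.08, adjusted p = 0.307). Cyp2e1 (2.55 ± 0.35) and Cyp1a2 (2.41 ± 0.10), both cytochromes of the pericentral zone, rose from low readings of 4.32 ± 0.25 and 2.94 ± 0.15, the Wnt feedback gene Nkd1 rose by 0.63 ± 0.10 and Lect2 fell by 1.45 ± 0.26 on the log2 scale. The other falls of this list were in brighter genes. Glul went from 8.83 to 7.93 (-0.91 ± 0.21, adjusted p = 0.0376) and Gstm3 from 8.24 to 7.61 (-0.63 ± 0.15, adjusted p = 0.0441). Among 13 periportal genes 2 rose and 3 fell (2 and 4 when adjusted over the list alone): Cyp2f2 rose by 1.53 ± 0.24, and Etnppl (-1.86 ± 0.27), the protease gene Ctsc (-1.55 ± 0.24) and Hsd17b13 (-1.04 ± 0.19) fell. The periportal median of 0.11 opposed the mean of -0.11 and the test's direction (adjusted p = 0.811). By fry, which asks whether the genes of a list move one way on balance, the pericentral list pointed up (false discovery rate 0.00421). The range was 0.0042 to 0.49 over its alternatives. As many members fell as rose, and Cyp1a2 read 5.34 on each 6-week array (SD 0). Whether Cyp1a2 alone carried the result was not tested. Lect2 lost its call without any 1-week array, Cyp2f2 without 1-week array 2 or 3, Nkd1 without 1-week array 2 or 6-week array 3, Etnppl without 1-week array 3 or 6-week array 3, Ctsc without 6-week array 3 and Hsd17b13 without any array but 6-week array 1 (adjusted p up to 0.089, 0.065, 0.053, 0.053, 0.055 and 0.084).

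Several genes of the fetal liver were lower at 6 weeks. Afp, the alpha-fetoprotein gene, fell from 6.60 ± 0.36 to 3.80 ± 0.20 (-2.80 ± 0.20, adjusted p = 0.00116), and the RNA-binding protein gene Igf2bp3 (-1.64 ± 0.16) and the imprinted genes Mest (-1.30 ± 0.16) and Peg3 (-1.25 ± 0.20) fell as well. Of 20 measured members 1 rose and 5 fell (1 and 8 when adjusted over the list alone), with a median of -0.26. The list passed (adjusted p = 0.0137), with adjusted p = 0.48 with an estimated correlation, and lost the call without 6-week array 2 (0.0706), in a range of 0.0039 to 0.48 over its alternatives. In the same arrays the macrophage, neutrophil and stellate cell markers had medians of -1.31, -0.76 and 0.48. Peg3 lost its call without 1-week array 1 or 3 (adjusted p up to 0.062).

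Cell cycle genes had the lowest median of the 25 lists, -1.72. Of 32 measured members 0 rose and 22 fell (1 and 26 when adjusted over the list alone). Besides Mki67 and Ccnb2, Rrm2, of nucleotide synthesis (-2.77 ± 0.15), the cyclin gene Ccna2 (-2.67 ± 0.12) and the spindle assembly gene Tpx2 (-2.38 ± 0.10) fell, while Ccnd1, a cyclin gene of growth factor response, had 0.52 ± 0.19 (adjusted p = 0.128). Of the genes of the replicative helicase, Mcm4 fell by 0.56 ± 0.14 on the log2 scale and Mcm2 (-0.22 ± 0.17) did not pass. The call of Mcm4 was lost without any 1 array and with the block (adjusted p up to 0.13). The list passed (adjusted p = 7.34e-23), with adjusted p = 0.36 with an estimated correlation, and Mki67, Ccnb2, Rrm2, Ccna2 and Tpx2 kept their calls without each of the 6 arrays. In the same arrays the macrophage and neutrophil markers had medians of -1.31 and -0.76. Monocyte genes, a list chosen after the data were seen, had a median of -1.90.

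Lipid metabolism genes split by pathway. Of 17 measured genes of fatty acid oxidation, 0 rose and 11 fell (0 and 16 when adjusted over the list alone), with a median of -0.66: Pdk4, a kinase gene that spares glucose, fell by 1.31 ± 0.13 on the log2 scale. The acyl-CoA dehydrogenase genes Acadm and Acadl fell by 0.84 ± 0.14 and 0.66 ± 0.14, and Hadhb by 0.92 ± 0.19. Of 15 measured genes of cholesterol synthesis, 10 rose and 0 fell (12 and 0 when adjusted over the list alone), with a median of 1.20, among them Idi1 (2.64 ± 0.36, and 1.77 ± 0.27 on a second probe set), Cyp51 (1.86 ± 0.29), Fdps (1.40 ± 0.22) and Nsdhl (1.36 ± 0.18). Of 19 lipogenesis genes 4 rose and 1 fell (6 and 2 when adjusted over the list alone; median 0.04, adjusted p = 0.395): the desaturase genes Fads1 (1.34 ± 0.22) and Fads2 (1.31 ± 0.25) and the fatty acid synthase gene Fasn (1.02 ± 0.21) rose, and Pparg, the gene of the adipogenic nuclear receptor, fell by 1.71 ± 0.17 on the log2 scale. Both other lists passed, fatty acid oxidation with adjusted p = 1.87e-09 and cholesterol synthesis with adjusted p = 8.72e-07, against adjusted p = 0.36 and adjusted p = 0.48 with an estimated correlation. In the same arrays the macrophage and stellate cell markers had medians of -1.31 and 0.48, and immediate early genes 0.71. Pdk4, Idi1, Nsdhl and Pparg kept their calls without each array. Cyp51 and Fdps lost them without 1-week array 1 or 3 and Acadm without any 1-week array or 6-week array 2. Acadl lost it without 1-week array 1 or 3 or 6-week array 2 or 3, Hadhb without any array but 6-week array 1. Fads1 and Fasn lost it without any 1-week array or 6-week array 3, and Fads2 without any array but 6-week array 2 (highest adjusted p 0.11, for Fasn).

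Immediate early genes, which respond to growth factors and to tissue dissociation, were higher at 6 weeks. Of 19 measured members 7 rose and 0 fell (12 and 0 when adjusted over the list alone), with a median of 0.71, among them Ier3 (1.06 ± 0.09), Jun (1.57 ± 0.32), Atf3 (1.52 ± 0.27) and Ier2 (0.73 ± 0.17). The list passed (adjusted p = 0.000231), with adjusted p = 0.48 with an estimated correlation and a false discovery rate of 0.0613 by fry, in a range of 1e-06 to 0.48. Macrophage, neutrophil and stellate cell markers had medians of -1.31, -0.76 and 0.48 in these arrays. Of 17 clock genes 4 rose and 1 fell (6 and 2 when adjusted over the list alone; median 0.20, adjusted p = 0.294): Bhlhe40 (1.69 ± 0.17), Dbp (1.36 ± 0.32) and Nr1d2 (0.96 ± 0.18) rose and Arntl, the gene of the activating partner of Clock, fell by 0.93 ± 0.19 on the log2 scale. Ier2 missed the threshold with the block (adjusted p = 0.0653). Without 1 array, Ier3 and Bhlhe40 kept their calls throughout. Jun, Ier2, Arntl and Dbp kept them only without 6-week array 1, Atf3 lost it without any 1-week array or 6-week array 3, and Nr1d2 without 1-week array 1 or 2 or 6-week array 2 or 3 (adjusted p up to 0.15, for Ier2).

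Of 22 measured acute phase and inflammatory genes, 3 rose and 0 fell (3 and 0 when adjusted over the list alone), with a median of 0.27 (adjusted p = 0.42). The C-reactive protein gene Crp rose by 0.95 ± 0.19, the chemokine gene Ccl2 by 1.52 ± 0.34 and the adhesion gene Icam1 by 0.56 ± 0.13, and Nfkbia had 0.38 ± 0.11 (adjusted p = 0.0731, with 0.046 to 0.2 over its alternatives). Of 16 interferon response genes 0 rose and 2 fell (0 and 3 when adjusted over the list alone), with a median of -0.30: the immunoproteasome gene Psmb9 (-1.03 ± 0.18) and Bst2, which tethers budding virus (-0.61 ± 0.12). Irf7 (-1.30 ± 0.35) and Oasl2 (-0.88 ± 0.30) did not pass, but did with the block (adjusted p = 0.0176 and 0.033). Irf7 also passed in 4 other alternatives and Oasl2 without 1-week array 1 (0.0378), in ranges of 0.018 to 0.17 and 0.033 to 0.27. The interferon list passed (adjusted p = 0.00462), with adjusted p = 0.49 with an estimated correlation, and lost the call with bright probe sets only (0.127) and by fry (0.109), in a range of 0.00047 to 0.49, in arrays where the macrophage markers had a median of -1.31. Its own median lay at percentile 3.6 of random lists matched on mean expression, inside their central 95% (-0.32 to 0.11). Icam1 missed the threshold with the block (0.0501) and after median centring (0.0513), and Ccl2 with array weights (0.0574). Icam1 and Bst2 kept their calls only without 6-week array 1 and Ccl2 only without 1-week array 3, Crp lost it without 1-week array 1 or 2 or 6-week array 2 or 3, and Psmb9 without 1-week array 3 or 6-week array 3 (adjusted p up to 0.12, 0.10, 0.12, 0.11 and 0.062).

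Genes of TGF-beta signalling and mesenchymal transition moved both ways. Of 20 measured members 3 rose and 4 fell (4 and 6 when adjusted over the list alone): the transcription factor gene Zeb2 (-1.45 ± 0.18), the intermediate filament gene Vim (-1.16 ± 0.19) and the receptor gene Tgfbr1 (-0.71 ± 0.15) fell, and Tgfb3 rose by 0.80 ± 0.11. The list had a median of 0.09 and a mean of 0, beside a median of 0.04 over all genes. The competitive test, which compares with all other genes and not with 0, pointed down (adjusted p = 0.825). Its direction turned in several alternatives. Stellate and macrophage markers had medians of 0.48 and -1.31 in the same arrays. Vim lost its call without 1-week array 2 or 3 and Tgfbr1 without any array but 6-week array 1 (adjusted p up to 0.074 and 0.11).

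Markers of liver cells other than hepatocytes and duct cells went in different directions. Of 17 macrophage and Kupffer cell markers, 0 rose and 10 fell (0 and 13 when adjusted over the list alone), with a median of -1.31. The complement gene C1qc fell from 10.34 ± 0.34 to 8.99 ± 0.28 (-1.35 ± 0.21), Cd68 by 1.54 ± 0.19, the Fc receptor gene Fcgr1 by 1.86 ± 0.29 on the log2 scale, and the integrin gene Itgam from 6.81 ± 0.43 to 4.83 ± 0.19. Of 12 neutrophil markers, 0 rose and 4 fell (0 and 7 when adjusted over the list alone), with a median of -0.76, including Retnlg (-3.48 ± 0.33), Ngp (-1.91 ± 0.22), Mpo (-1.07 ± 0.13) and the lactoferrin gene Ltf (-0.68 ± 0.16). Of 16 lymphocyte markers, 0 rose and 2 fell (0 and 2 when adjusted over the list alone), with a median of -0.30: the cytotoxic granule gene Gzma (-2.22 ± 0.37) and Ptprc, the gene of the leukocyte antigen CD45 (-1.76 ± 0.31), while the B cell gene Cd79b (-0.48 ± 0.17) and the T cell gene Cd3d (-0.31 ± 0.15) did not pass. The lists passed with adjusted p = 2.11e-09, 0.000231 and 0.0137, and had adjusted p = 0.40, adjusted p = 0.36 and adjusted p = 0.54 with an estimated correlation. The lymphocyte list lost the call without 1-week array 3 (0.13) or 6-week array 1 (0.17) and by fry (0.233), in a range of 0.0012 to 0.54. Ltf kept its call only without 1-week array 1, and lost it with array weights (0.0698) and without the intensity trend (0.053), in a range of 0.014 to 0.15. Cd68, Itgam, Retnlg, Ngp and Mpo kept their calls without each array. C1qc lost it without 1-week array 1 or 2 or 6-week array 3, Fcgr1 without any 1-week array, Gzma without 1-week array 2 or 3 or 6-week array 3, and Ptprc without any 1-week array or 6-week array 3 (adjusted p up to 0.062, 0.064, 0.082 and 0.089).

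Stellate cell and fibroblast markers were higher. Of 18 measured members 9 rose and 0 fell (11 and 0 when adjusted over the list alone), with a median of 0.48. Dcn rose from 6.37 ± 0.48 to 9.20 ± 0.23, Rgs5 from 3.78 ± 0.02 to 6.59 ± 0.10, the retinol-storing enzyme gene Lrat from 3.04 ± 0.22 to 5.23 ± 0.53 (2.19 ± 0.27) and the matrix gene Reln by 1.28 ± 0.10, all of which kept their calls without each array. Of the collagen genes of the list, Col14a1 rose by 0.97 ± 0.13, and values were 0.88 ± 0.17 for Col3a1 (adjusted p = 0.0212), 0.50 ± 0.15 for Col1a2 (adjusted p = 0.0871) and 0.35 ± 0.12 for Col1a1 (adjusted p = 0.0995), and Col3a1 lost its call without 1-week array 1 or 2 or 6-week array 3 (adjusted p up to 0.089). The list passed (adjusted p = 1.09e-08), with adjusted p = 0.36 with an estimated correlation. Of 18 endothelial markers 4 rose and 1 fell (5 and 3 when adjusted over the list alone; median 0.32, adjusted p = 0.212): the sinusoidal lectin gene Clec4g (2.27 ± 0.22), Flt4 (0.80 ± 0.10) and Eng (0.80 ± 0.11) rose and Emcn fell by 0.86 ± 0.15 on the log2 scale. A second, dim probe set of Clec4g had 0.19 ± 0.08 (adjusted p = 0.238 over probe sets). The endothelial list passed after quantile normalization (0.0193) and with bright probe sets only (0.0291), in a range of 0.019 to 0.66, and Emcn lost its call without 1-week array 1 or 3 (adjusted p up to 0.076).

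No erythroid or sex-linked gene passed. The 9 erythroid markers had a median of 0.07 (0 and 0 past the test when adjusted over the list alone; list adjusted p = 0.513), with Hbb-y at 0.29 ± 0.16, Slc4a1 at 0.15 ± 0.10, Alas2 at 0.14 ± 0.10 and Tfrc at -0.36 ± 0.24. The 4 sex-linked genes had a median of -0.04 (0 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.608). The X-inactivation transcript Xist read 2.48 ± 0.09 and 2.54 ± 0.08, and the Y-linked gene Eif2s3y 7.45 ± 0.16 and 7.01 ± 0.12, which passed with bright probe sets only (adjusted p = 0.0414, with 0.041 to 0.17 over its alternatives). The other Y-linked genes, Kdm5d (0.19 ± 0.17) and Uty (-0.14 ± 0.15), did not pass.

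**Figure D3:**
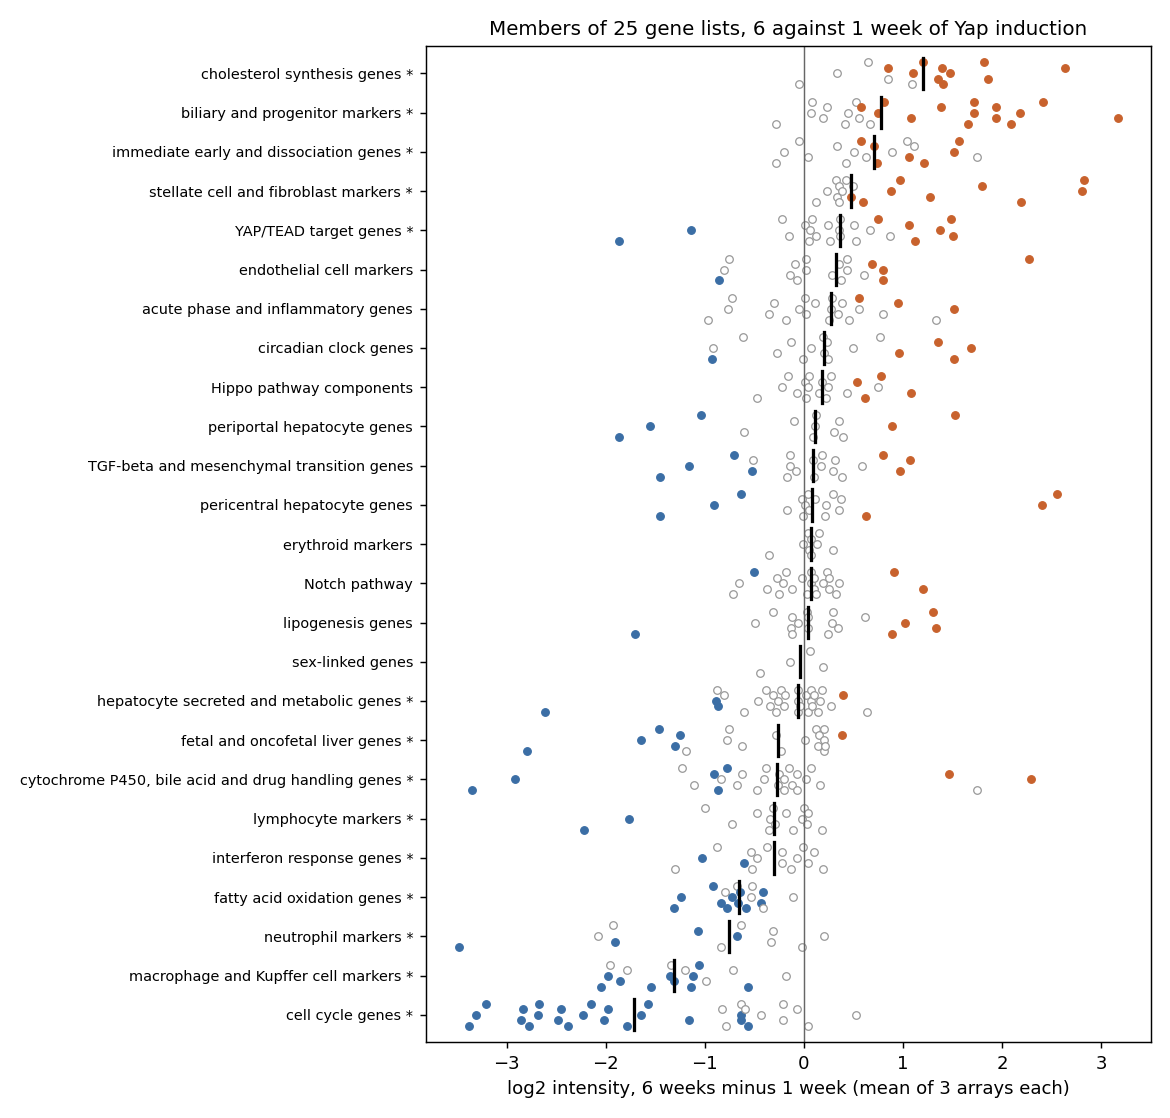
Differences of log2 intensity, 6 weeks minus 1 week (horizontal axis), of the measured members of 25 gene lists, ordered by median. Filled points passed an adjusted p of 0.05 over all genes (orange higher, blue lower at 6 weeks), open points did not, black bars are list medians, and stars mark the 14 lists past the competitive test with a preset correlation, from cholesterol synthesis (median 1.20) to the cell cycle (-1.72).

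Of the 25 lists, 14 passed the competitive test with a preset correlation between genes of 0.01, 5 higher and 9 lower at 6 weeks. With a correlation estimated for each list 0 of the 25 passed, and the smallest adjusted p was 0.36. By fry, 10 lists moved one way on balance, 9 of them among the 14. Against random lists matched on mean expression, 4 lists that did not pass had high medians. These were the acute phase (percentile 100), endothelial (99.99), Hippo (99.68) and clock lists (99.06). The other lists that did not pass lay inside the central 95%. Matching takes no account of correlation between the genes of a list.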

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

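The tests chosen only after the result was seen were those of macrophage RNA loss, of the share of the main cell type, of the makeup of the macrophages, of single cell cycle genes against Adgre1 and of the time of day; the others were set beforehand. The comparisons above used probe sets with 1 gene symbol. Among the other 13120 probe sets, which have several symbols or none, 390 passed the threshold in a fit over all probe sets, 159 higher and 231 lower at 6 weeks. That is 2.97%, against 6.25% of the probe sets with 1 symbol, and these signals are outside the named genes.

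Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 2242 genes, and the highest of the others gave 0. For gene lists, 1 split gave as many as 14, again the real one, and the others gave 2 to 10. The list test with a preset correlation thus called lists in each of the other splits, where 0 genes passed. Those splits mix the times unevenly, so they are not free of the difference between them. With 10 splits the share cannot go under 0.05. Of the 4 splits that part all pairs of equal replicate number, the real one called 2242 genes and the others 0.

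Cell cycle genes were lower at 6 weeks, with a list median of -1.72. The narrower value range of the 6-week arrays does not account for it: the median lay at percentile 0 of 10000 random lists matched on mean expression, whose central 95% ran from -0.20 to 0.09. A loss of macrophage RNA alone is not settled by the medians, where the cell cycle lay -0.41 from the macrophage markers (two-sided permutation p = 0.47). By the criterion as first written a gap with such a p counts in favour of that loss; a criterion added later does so only for a gap under 0.1 in size, and by it the larger gap here leaves the loss open. Single genes do not settle that loss either. Of 32 cell cycle genes, 13 fell further than Adgre1 (-2.05), the largest fall of the macrophage list. For 10 of them the 95% interval lay below that value, with the error of Adgre1 left aside. Monocyte genes, a list chosen after the data were seen, also fell further than Adgre1, such as Chil3 (-2.89) and Ms4a6c (-2.62). Of the 13 monocyte genes 10 fell and 0 rose, with a median of -1.90. The sort for Yap-expressing cells does not decide it, since C1qc read 10.34 in the sorted 1-week samples. Loss of a dividing subset and less division of the sorted cells both stay open.

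Macrophage markers were lower and stellate cell markers higher, 1.79 apart in median. The two-sided permutation p was 1e-05, the smallest that 100000 permutations give, over genes, which are not independent. Correlations estimated within the lists were 0.64 and 0.19, and neither list passed the competitive test with them (adjusted p = 0.40 and adjusted p = 0.36). All 17 macrophage markers lay below 0 and all 18 stellate cell markers above 0. These counts are not matched on expression. At 1 week, 16 of the macrophage but only 2 of the stellate cell markers read log2 6 or more. Genes with a mean that bright had a median of -0.13 and dimmer genes 0.07. A change in the share of the main cell type alone would move the markers of other types alike, which the gap of 1.79 argues against. That gap lay at percentile 100 of gaps between matched random lists (-0.07 to 0.46), which argues against the narrower value range. Fewer macrophages of the same makeup behind the sort gate for Yap-expressing cells may be one source of the fall, and the test does not settle it: 3 of 17 markers (Lyz2, Itgam and Csf1r, whose own call was lost without any 1 array at an adjusted p up to 0.12) differed from the list's median by more than their 95% interval, at an exact one-sided binomial p of 0.05, the threshold itself, which meets neither outcome written for the test, and the band in which such a p is read as open was added after it was seen. Abundant macrophage genes went from 10.34 to 8.99 (C1qc) and from 9.39 to 7.85 (Cd68), while Lyz2 had 10.67 and 10.49, and 0 markers of these lists are in another list. A change of gene use within the sorted cells stays open as well.

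Cholesterol synthesis genes were higher and fatty acid oxidation genes lower, 1.86 apart in median. This gap lay at percentile 100 of gaps between matched random lists (-0.31 to 0.34), which argues against the narrower value range. Collection at another time of day may contribute and stays open: 8 clock genes of one phase had a mean of 0.62 and 4 of the opposite phase -0.42, a gap of 1.04 (two-sided exact permutation p = 0.016 over genes, which are not independent). These were chosen after the result from 17 clock genes, and of the 5 left out Per1 (-0.91 ± 0.26) ran against its phase: with Per1 added to the 8 the exact permutation p was 0.063, and with all 5 added 0.032. The labels give no time of collection, and the length of Yap expression stays open as untested.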

How the results depend on the processing

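All alternatives here were set before the data were examined. The count of 2242 genes (952 higher, 1290 lower) became 610 (238 and 372) at an adjusted p of 0.01, 869 (288 and 581) with a minimum of 2-fold, and 296 (131 and 165) by a plain two-sample test per gene, which by construction takes less from the other genes or asks for more. With 1 array left out it ran from 707 to 2396 genes (261 to 942 higher, 446 to 1454 lower), where fewer arrays enter the test. Called genes were 42.5% higher, against 47.8% after quantile normalization and 33% after median centring. With the replicate number as a block 2363 genes passed, 1878 of them shared with the fit without it; apart from the calls named above and 14 lists kept of 14, the block changed no other call of a named gene or list. With an estimated correlation 0 lists passed. The estimates for the 14 lists ran from 0.06 (YAP/TEAD targets) to 0.70 (cholesterol synthesis), against the preset 0.01. A higher correlation raises the p by construction, and what else contributed was not tested. The Notch list turned direction without the intensity trend (adjusted p = 0.915), with array weights (0.984), after quantile normalization (0.815) or median centring (0.903), with bright probe sets only (0.623), with the mean of a gene's probe sets (0.992), by fry (0.504) and with each of 3 arrays left out (0.786 to 0.972 over all 6). The periportal list did so after median centring (0.999) and without 1-week array 1 (0.474 to 0.98 over all 6), and the TGF-beta list after quantile normalization (0.827), median centring (0.947), with bright probe sets only (0.507) and without 6-week array 2 (0.636 to 0.997 over all 6). None of these passed in any setting, and the cause was not tested. Log2 differences ran from -0.24 to 0 for Uty and from -0.02 to 0.23 for Ccn2 with 1 array left out, which turned the sign of both. Robust eBayes has no counterpart in the list test, and probe sets in place of genes were run for the counts alone. Signal over background limits genes near the median log2 intensity of 3.98, whose differences are compressed.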

Other observations

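The gene groups of this part were chosen after the data were seen, so all their tests are descriptions, and the members were picked knowing some of the values. Ces1d, Ces1g, Wfdc2, Plet1 and Cdh6, of the 12 largest rises, are counted in these groups. So are Chil3 and Fabp2, of the 12 largest falls. The counts of the groups thus partly return genes already picked for their size of change. Carboxylesterases, which hydrolyse lipid esters and drugs, rose in 8 of 14 measured members, and 0 fell (median 0.83). Ces1c went up by 1.85 ± 0.11 (log2 difference ± SE, n = 3 arrays per time; adjusted p = 0.000797) and Ces1f by 0.96 ± 0.09, beside Ces1d and Ces1g, while Ces2a had -0.54 ± 0.30 and Ces2e -0.05 ± 0.18. Genes of tight junctions and apical epithelium rose in 11 of 20 members, and 0 fell (median 0.66): the serine protease gene St14 by 1.87 ± 0.24, Prr15l by 2.12 ± 0.27, cingulin (Cgn) by 1.07 ± 0.09 and the tricellulin gene Marveld2 by 0.79 ± 0.10. These 6 genes with a rise kept their calls without each array. With an estimated correlation both lists had adjusted p = 0.076. The 11 members that rose include Wfdc2, Plet1 and Cdh6, and junction genes that did not pass include Tjp1 (0.11 ± 0.09) and Cldn1 (-0.48 ± 0.24).

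Monocyte genes fell in 10 of 13 members and rose in 0 (median -1.90, adjusted p = 0.076 with an estimated correlation), among them Ms4a6c (-2.62 ± 0.18), Cd300a (-1.89 ± 0.20) and the fractalkine receptor gene Cx3cr1 (-1.32 ± 0.18). MHC class II genes, which antigen-presenting cells express, did otherwise: 4 of 8 rose and 1 fell (median 0.52; list adjusted p = 0.108), with 0.97 ± 0.18 for H2-Aa, 1.03 ± 0.21 for H2-Ab1 and 0.96 ± 0.21 for Cd74, and -0.80 ± 0.18 for H2-DMa. H2-Ab1 and Cd74 kept the call only without 1-week array 3, H2-DMa lost it without any 1 array (adjusted p up to 0.11), and H2-Aa lost it without 1-week array 1 or 2 or 6-week array 2 or 3 (adjusted p up to 0.12, 0.13 and 0.092 for H2-Ab1, Cd74 and H2-Aa). The metallothionein genes Mt2 and Mt1, which respond to zinc and glucocorticoids, fell by 2.70 ± 0.30 and 1.63 ± 0.20 on the log2 scale and kept their calls without each array, while the list of 6 had a median of -0.06 (adjusted p = 0.365).

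Glycolysis genes moved both ways, 3 of 15 higher and 4 lower (median -0.27, adjusted p = 0.0348, or adjusted p = 0.34 with an estimated correlation). The hepatic pyruvate kinase gene Pklr rose by 0.93 ± 0.14 and the lactate dehydrogenase gene Ldha fell by 1.24 ± 0.18 on the log2 scale; Pklr lost its call without 1-week array 1 or 2 and Ldha without 1-week array 2 or 3 (adjusted p up to 0.052 and 0.063). Of 16 primary cilium genes 1 rose and 0 fell (median 0.29, adjusted p = 0.0181, or adjusted p = 0.32 with an estimated correlation), the intraflagellar transport gene Ift81 (0.84 ± 0.17), which lost its call without any 1-week array or 6-week array 3 (adjusted p up to 0.11). Of 11 genes induced by peroxisome proliferators or of ketone metabolism, 1 rose and 4 fell (median -0.27, adjusted p = 0.0348, or adjusted p = 0.16 with an estimated correlation), with -1.61 ± 0.31 for Angptl4, which lost its call without any 1-week array or 6-week array 2 (adjusted p up to 0.10).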
